A study of Mus musculus with 34 samples.

How the data were processed

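The samples were mouse thoracic spinal cord from trkB.T1 wild-type (WT) and trkB.T1 knockout (KO) animals on C57BL/6J (>N20), 8–12 weeks old, labelled sham or taken at day 1, day 3 or day 7 after a moderate contusion injury. Titles and source names call the control arrays sham, while their description codes begin with Nav. Whether those animals had a sham operation or none is not given in the sources used here, so "sham" stands for the labelled control group throughout. Per the labels, total RNA was extracted with Trizol, 1 µg was made into biotinylated cRNA by the Affymetrix protocol, and the arrays were biological replicates. There were 34 arrays: sham WT 4, day 1 WT 5, day 3 WT 4, day 7 WT 4, sham KO 4, day 1 KO 4, day 3 KO 5 and day 7 KO 4. The deposited values were used as given: per the submitters' processing notes they were computed by GCRMA, whose version was not stated, and per the labels they are in log2 units. The values ran from 2.17 to 15.904, array medians from 4.139 to 4.39, and 33.7% of all values lay within 0.1 of the lowest value, so that differences between genes near that floor cannot be measured, and a difference from a group at or near the floor is a lower bound. No 2 arrays were identical (0 pairs). The number of arrays per group limits precision.

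Arrays were grouped by their titles. The arrays titled day 1 WT replicates 1 and 2 carry other words in their source and time fields (day 7 for replicate 1, sham for replicate 2), while title and description both say day 1 WT. The title was followed, and both other readings were run as alternatives. In a comparison of each array with the group means, 34 of 34 arrays were nearest to their own time point and 21 to their own group of time and genotype. Day 1 WT replicate 1 correlated at 0.796 with the day 1 WT mean and at most at 0.159 with a group of another time. For replicate 2 these were 0.689 and 0.13. These values argue against the source and time fields of both arrays. Counts under that grouping thus place day 1 arrays among sham and day 7.

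Of 45101 probe sets, 64 were array controls. Probe sets with a log2 value of at least 4 in at least 4 arrays were tested, 24628 in all, of which 20933 named exactly 1 gene and stood for 11999 genes. Gene names came from the platform table and were matched by Entrez identifier to the RefSeq table of assembly GRCm38.p6, which was used for names and for the order of genes around Ntrk2 only. The array files name no genome build, and the position of a probe set within its gene is not given in the sources used here.

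A linear model with 8 group means was fitted to all 34 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes, 26 residual degrees of freedom, 2.62 prior degrees of freedom). The comparisons were KO against WT in sham and at day 1, day 3 and day 7, the mean of these 4 differences, each injured time point against sham within each genotype, and the injury-by-genotype difference at each time point. Adjusted p-values are Benjamini-Hochberg values over all probe sets of a comparison, with a threshold of 0.05, and a fold threshold of 1.5 was used for a second count. Counts of probe sets called between genotypes include those of Ntrk2, the gene changed in the KO. Standard errors (SE) are limma's; group values are means ± SD over arrays. Where a gene had several probe sets, the probe set with the highest mean over all arrays stood for it.

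The gene lists, 36 in number, were written by hand for cell types and processes of the injured cord, and 33 of them had at least 5 tested members. Each was compared with all other genes by camera with a preset correlation of 0.01 and again with the correlation estimated from the arrays, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts of called members are given with adjustment over all probe sets and, separately, adjusted over the list alone. Lists for G1/S, DNA replication and G2/M were also pooled into a proliferation set of 67 named genes, 63 of them tested, whose mean per array was compared between genotypes by an exact two-sided permutation test. Groups, comparisons, filter, thresholds, gene lists, the rule for named genes and the alternatives not marked as later additions were set before the data were examined.

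The named genes were chosen by rule. All Ntrk2 probe sets were named. For KO against WT, its mean over conditions and the injury-by-genotype differences, these were the 10 largest positive and the 10 largest negative log2 differences among genes past the threshold, or with fewer than 3 such genes also the 5 with the smallest p. For each injured group against sham these were the 5 largest in each direction, and for each list described, the 4 members with the largest absolute difference, some of which are left unnamed where they repeat.

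The fit was tested on simulated data: with log2 changes of 1 planted in 67 probe sets, 95.5% were called for KO against WT at day 1, 71.6% in sham and 68.7% for injury by genotype at day 1, and with log2 changes of 0.5 the shares were 43.3%, 50.7% and 20.9%. The simulated noise was independent between genes, with the same spread in all groups and no floor. The real arrays differ in each of these, so the shares are rough guides. Alternatives tried were no filter, a stricter filter (log2 of at least 6), an intensity trend with a robust prior, array weights, quantile normalization, centring on the array median, both treatments of the conflicting labels, a replicate block, a fit of only the arrays compared, list values from the mean of a gene's probe sets, and leaving out each array. After the data were examined, a fit without 3 arrays that stood apart and a fit with the day 7 KO arrays averaged were added. A covariate for sex was not run, since sex-linked genes showed the same pattern in all 34 arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.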

Results

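The series compares trkB.T1 WT and trkB.T1 KO mice in thoracic spinal cord of controls labelled sham and at day 1, day 3 and day 7 after a moderate contusion. Ntrk2 encodes TrkB, the receptor for brain-derived neurotrophic factor, and trkB.T1 is its truncated form without the kinase domain, the main TrkB form of astrocytes. The design asks how loss of this form changes the cord at rest and its response to injury. The first 2 principal components of the 34 arrays held 52.3% and 17.9% of the variance, and all 34 arrays lay nearest to their own time point.

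Ntrk2 signal was lost from the KO cords on 2 of its 6 tested probe sets. On 1420838_at the WT arrays ran from 10.193 to 10.667 in sham, 10.008 to 10.358 at day 1, 10.464 to 10.818 at day 3 and 10.475 to 10.854 at day 7. The KO arrays ran from 3.307 to 9.463, 3.784 to 4.765, 3.123 to 4.938 and 3.957 to 4.528. On 1435196_at the WT arrays ran from 9.579 to 9.84, 9.025 to 9.342, 8.645 to 9.42 and 9.657 to 9.915. All KO arrays read the lowest value of that probe set, 2.826, except the library labelled sham KO replicate 2. That library read 9.463 on 1420838_at and 8.591 on 1435196_at. The other sham KO arrays read 3.307, 4.617 and 4.907 on the former. The KO minus WT differences (log2 ± SE) on 1420838_at were −4.82 ± 0.66 in sham (adjusted p = 0.00033), −6.11 ± 0.63 at day 1 (adjusted p = 3.64e-07), −6.76 ± 0.63 at day 3 (adjusted p = 3.33e-07) and −6.46 ± 0.66 at day 7 (adjusted p = 1.51e-06). On 1435196_at they were −5.45, −6.31, −6.26 and −6.91 (adjusted p = 1.57e-13 over the 4 conditions), which are lower bounds in size, since KO arrays lay at the floor of that probe set. Without the library labelled sham KO replicate 2 the sham differences were −6.11 on 1420838_at and −6.90 on 1435196_at. For the sham group alone the fit of only the arrays compared gave −4.82 (adjusted p = 0.408) and −5.45 (adjusted p = 0.398).

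The other bright Ntrk2 probe sets kept their signal in KO cords. On 1435305_at the KO arrays averaged 10.59 ± 0.06 in sham, 10.11 ± 0.19 at day 1, 9.53 ± 0.54 at day 3 and 10.09 ± 0.05 at day 7. The WT arrays averaged 10.33 ± 0.06, 9.54 ± 0.29, 9.09 ± 0.28 and 9.43 ± 0.14. Its mean difference over the 4 conditions was +0.48 ± 0.09 (adjusted p = 0.0182), with no call at any single condition (+0.26, +0.56, +0.44 and +0.66, adjusted p = 1, 0.193, 0.415 and 0.611). The mean differences of 1437560_at (+0.49, adjusted p = 0.0537, or 0.047 with an intensity trend and a robust prior), 1458622_at (+0.42, adjusted p = 0.125) and 1446712_at, which lay near the floor (−0.08, adjusted p = 0.82), did not pass. After injury 1435305_at fell in both genotypes: by log2 −0.78, −1.24 and −0.90 in WT and −0.48, −1.06 and −0.50 in KO at day 1, day 3 and day 7. The 2 probe sets lost in KO did not pass for the injury-by-genotype difference (1420838_at −1.30, −1.94 and −1.65, adjusted p = 0.998, 0.78 and 1). They were called lower in KO at day 3 than in KO sham (−1.68, adjusted p = 0.0205, and −1.44, adjusted p = 0.0474), a comparison that contains the library labelled sham KO replicate 2. The probe sets 1420837_at and 1444121_at lay below the filter in every group.

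**Figure D1:**
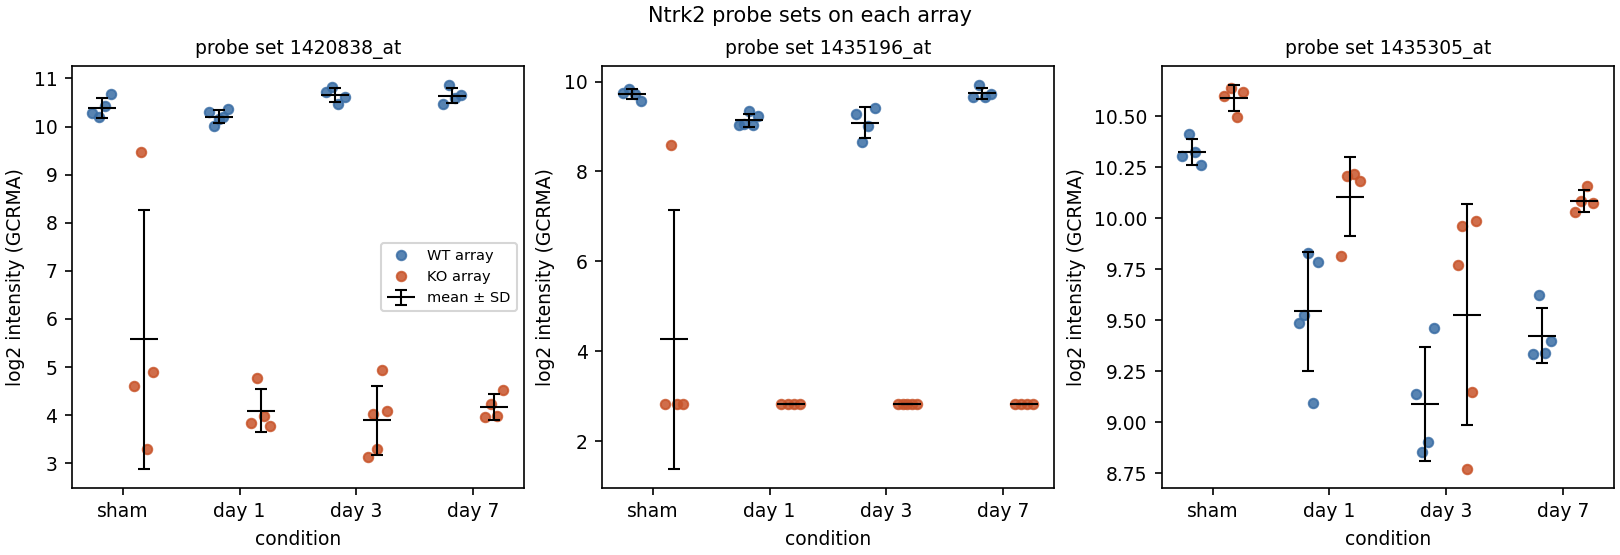
Log2 signal of the Ntrk2 probe sets 1420838_at, 1435196_at and 1435305_at (vertical axes) for each of the 34 arrays, as points by condition and genotype, with mean and SD per group. On 1435196_at the library labelled sham KO replicate 2 lay at 8.591 and all other KO arrays at 2.826.

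In WT cords, day 1 after injury brought macrophage, chemokine and reactive glial genes to high levels. The largest increases (log2 ± SE) were in Arg1, the arginase of wound macrophages (8.77 ± 0.42), Timp1, an inhibitor of matrix metalloproteinases (8.07 ± 0.24), Hmox1, which degrades heme (7.42 ± 0.33), Ccl2, the main monocyte attractant (6.87 ± 0.30), and Socs3, a feedback inhibitor of cytokine signalling (6.66 ± 0.26). Sham arrays lay near the floor for Arg1 (2.53 ± 0.32) and Timp1 (2.65 ± 0.64), so their differences are lower bounds. The largest decreases were in Aplnr, the apelin receptor (−3.75 ± 0.49), Dao, D-amino acid oxidase (−2.83 ± 0.17), P2ry12, the ADP receptor of resting microglia (−2.80 ± 0.31), Cpne4, a calcium-dependent membrane-binding protein (−2.74 ± 0.32), and Tdgf1, a co-receptor of Nodal (−2.68 ± 0.40). All 19 reactive astrocyte genes rose (19 adjusted over the list alone, mean 3.82), led by Ptx3 (6.19), Serpina3n (5.84) and Osmr (4.90), with adjusted p = 0.0173 with an estimated correlation. Of 20 chemokines and cytokines 18 rose (18 adjusted over the list alone, mean 3.32), among them Ccl12 (6.43) and Ccl3 (6.39), with adjusted p = 0.0777 with an estimated correlation. Of 13 complement and Fc receptor genes 12 rose (12 adjusted over the list alone, mean 2.62, adjusted p = 0.0777 with an estimated correlation). Neuronal genes fell, among them 12 of 15 glutamate and dorsal horn genes (12 adjusted over the list alone, adjusted p = 0.469 with an estimated correlation). So did 10 of 12 GABA and glycine genes (11 adjusted over the list alone, adjusted p = 0.439 with an estimated correlation) and 17 of 24 pan-neuronal genes (18 adjusted over the list alone, adjusted p = 0.579 with an estimated correlation), such as Syt1 of synaptic vesicles (−1.51). Of the 63 proliferation genes 46 rose (48 adjusted over the list alone, mean 1.18, p = 0.0532 with an estimated correlation for the pooled set). In all, 5917 probe sets were higher and 7113 lower than in WT sham, 6211 of them by at least 1.5-fold. With the 2 arrays with conflicting labels grouped by source and time the count was 5974.

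At day 3 in WT, genes of cell division were high alongside the inflammatory response. All 23 G2/M genes rose (23 adjusted over the list alone, mean 3.93, adjusted p = 0.0405 with an estimated correlation). All 22 DNA replication genes rose (22 adjusted over the list alone, mean 2.21, adjusted p = 0.0879 with an estimated correlation). Arg1 (9.30 ± 0.44), Hmox1 (8.37 ± 0.34), Gpnmb, a glycoprotein of phagocytic macrophages (8.14 ± 0.50), Timp1 (7.89 ± 0.26) and Ms4a6d (7.20 ± 0.27) rose most. Cpne4 (−3.08 ± 0.33), Nxph2, a secreted neurexin ligand (−2.82 ± 0.43), Sptssb, a subunit of sphingolipid synthesis (−2.79 ± 0.44), Dao (−2.73 ± 0.18) and Gjd2, the gap junction protein of neurons (−2.42 ± 0.35), fell most. All 15 cholesterol synthesis genes fell (15 adjusted over the list alone, mean −1.07, adjusted p = 0.164 with an estimated correlation), among them Fdps (−1.94), Idi1 (−1.80) and Mvd (−1.45). Of the 24 pan-neuronal genes 23 fell (23 adjusted over the list alone, mean −0.82, adjusted p = 0.357 with an estimated correlation). In all, 6433 probe sets were higher and 8784 lower, 8828 by at least 1.5-fold.

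By day 7 in WT, phagocyte and matrix genes averaged highest of the time points. The matrix arrays at day 7 (8.462 to 10.324) overlapped those at day 3 (8.857 to 9.711), and these time points were not compared directly. All 23 phagocytic and lysosomal genes rose (23 adjusted over the list alone, mean 4.41, adjusted p = 0.024 with an estimated correlation). So did all 13 complement and Fc receptor genes (13 adjusted over the list alone, mean 4.15, adjusted p = 0.024 with an estimated correlation). All 25 fibroblast and matrix genes (25 adjusted over the list alone, mean 2.81, adjusted p = 0.238 with an estimated correlation) rose too, among them Postn (4.49), a matrix protein of scars, and the collagen gene Col3a1 (4.08). Gpnmb (10.52 ± 0.50), the macrophage-secreted Cd5l (7.30 ± 0.38), the complement receptor gene C3ar1 (7.24 ± 0.25), the regeneration-associated Sprr1a (7.01 ± 0.36) and Clec7a, a phagocyte lectin (6.95 ± 0.37), rose most. The values of Cd5l and Sprr1a are lower bounds, with sham means of 2.32 and 2.53. Cpne4 (−2.54 ± 0.33), Hoxd1 (−2.26 ± 0.17), Nwd2 (−2.26 ± 0.28), the neuropeptide gene Nmu (−2.20 ± 0.34) and Vwc2l (−2.17 ± 0.26) fell most. All 15 cholesterol genes fell (15 adjusted over the list alone, mean −1.42, adjusted p = 0.0924 with an estimated correlation). In all, 5379 probe sets were higher and 7794 lower, 7003 by at least 1.5-fold. Across all these comparisons, the difference between the 3′ and 5′ actin control probe sets, a sign of RNA quality, moved with the time point (log2 1.97 in WT sham, 1.72 at day 1, 1.49 at day 3 and 1.85 at day 7, 2.08, 1.77, 1.49 and 1.94 in KO). The same difference for Gapdh moved the other way from sham (0.07 in WT sham, then 0.29, 0.21 and 0.41, with 0.10, 0.27, 0.28 and 0.44 in KO). Day 7 WT replicate 4 stood apart, at 1.45 for actin and 0.106 for Gapdh. The other day 7 WT arrays read 1.93 to 2.019 and 0.456 to 0.57.

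KO cords responded to injury with largely the same genes. At day 1 the largest increases were in Arg1 (8.99 ± 0.44), Timp1 (8.02 ± 0.26), the scavenger receptor Msr1 (6.84 ± 0.29), Hmox1 (6.84 ± 0.34) and Ccl12 (6.60 ± 0.35). At day 3 they were in Arg1 (9.71 ± 0.42), Gpnmb (8.52 ± 0.48), Hmox1 (8.40 ± 0.33), Timp1 (8.07 ± 0.24) and the phagocyte lectin Clec4d (7.83 ± 0.33). At day 7 they were in Gpnmb (10.10 ± 0.50), C3ar1 (7.45 ± 0.25), galectin 3 (Lgals3, 7.38 ± 0.31), Clec7a (7.34 ± 0.37) and Cd5l (6.96 ± 0.38). Of these, Arg1 (2.33), Timp1 (2.41), Msr1 (2.55), Clec4d (2.61) and Cd5l (2.24) lay near the floor in KO sham, so their differences are lower bounds. In both genotypes 4423 probe sets were higher and 4888 lower at day 1 (1233 and 1683 expected by chance), 5719 and 7678 at day 3, and 4379 and 5862 at day 7, with 2, 6 and 4 called in opposite directions. The 2 responses correlated across probe sets with r of 0.917, 0.952 and 0.937, and probe sets are not independent replicates. Reactive astrocyte genes rose as a group at day 1 and day 7 (19 and 18 of 19, 19 and 19 adjusted over the list alone, adjusted p = 0.00862 and 0.032 with an estimated correlation).

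The largest decreases in KO cords after injury included skeletal muscle genes. At day 1 the skeletal muscle genes Tnnc2 (−6.34 ± 2.03), Myh1 (−5.44 ± 1.95), Acta1 (−5.40 ± 1.72), Tnni2 (−5.39 ± 1.62) and Myh4 (−5.21 ± 1.86) fell most. At day 7 these were Myh4 (−6.41 ± 1.86), Tnnc2 (−5.99 ± 2.03), Tnnt3 (−5.62 ± 1.77), Ckm (−5.18 ± 1.60) and Myl1 (−4.84 ± 1.86). At day 3 they were Hoxd10 (−3.09 ± 1.02), Ccser1 (−2.93 ± 0.43), Cpne4 (−2.85 ± 0.32), Sptssb (−2.83 ± 0.41) and Nxph2 (−2.59 ± 0.41). All 13 skeletal muscle genes fell at day 1 (13 adjusted over the list alone, mean −4.59, adjusted p = 0.673 with an estimated correlation) and 12 at day 7 (12 adjusted over the list alone, mean −4.46, adjusted p = 0.585 with an estimated correlation). The mean signal of that list was 9.38 ± 1.25 in KO sham, 6.40 ± 2.96 in WT sham and from 3.608 to 13.381 over all injured arrays. Its difference in response between genotypes did not pass with an estimated correlation (−3.14 at day 1, adjusted p = 0.819, −4.52 at day 7, adjusted p = 0.481). At day 1, 23 of the 63 proliferation genes rose in KO and 2 fell (mean 0.46), against 61 at day 3 (1 fell, mean 2.98) and 48 at day 7 (1 fell, mean 1.41), with p = 0.343, 0.00654 and 0.0359 with an estimated correlation for the pooled set. The test of the difference from WT is given with the injury-by-genotype comparison. In all, 10959 probe sets were called at day 1 (5133 higher, 5826 lower), 15964 at day 3 (6954 and 9010) and 11644 at day 7 (4900 and 6744). With the day 7 KO arrays averaged to 1 sample the day 7 count was 4205.

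**Figure D2:**
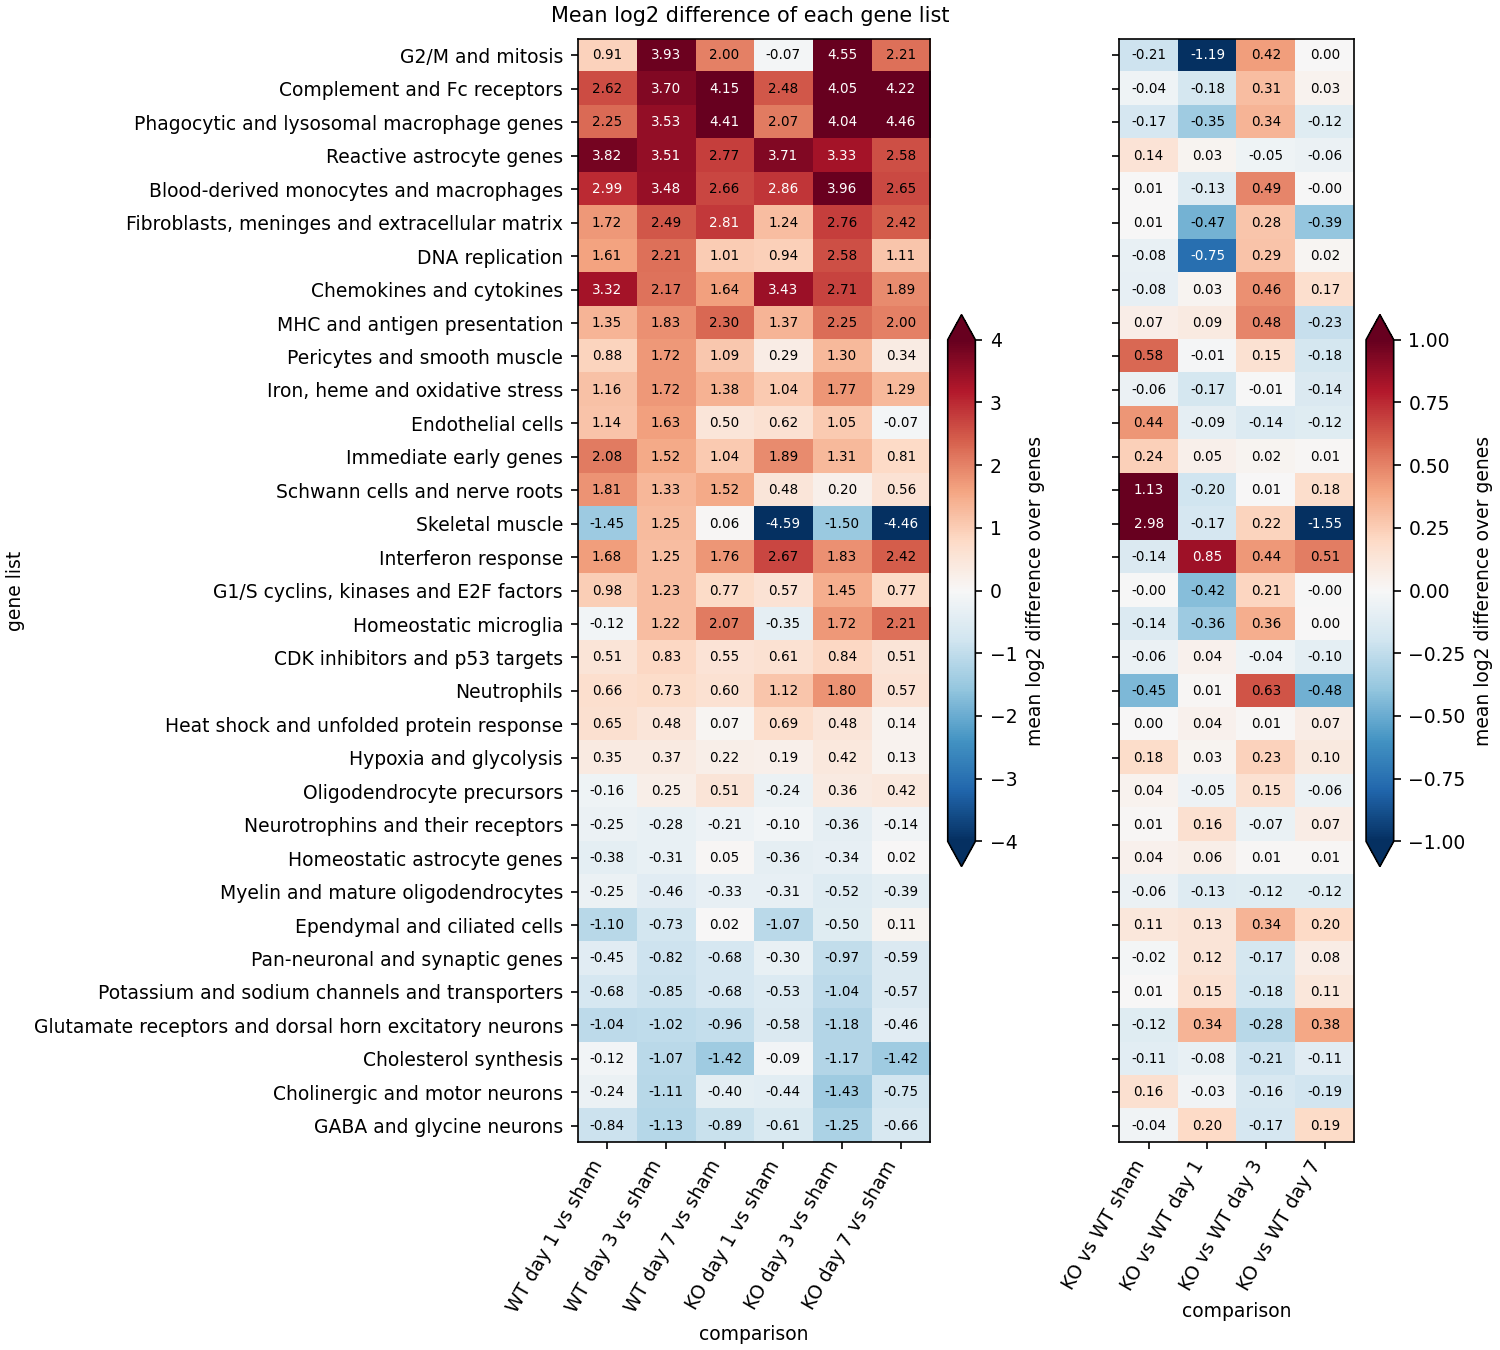
Mean log2 difference over the tested members of each of 33 gene lists (rows of the heat map) in the 6 comparisons of injured with sham cords on the left and the 4 comparisons of KO with WT on the right. Reactive astrocyte genes had means of 3.82, 3.51 and 2.77 in WT and 3.71, 3.33 and 2.58 in KO at day 1, day 3 and day 7.

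In sham cords, KO differed from WT in few genes, and 4 of the 8 genes named were caudal Hox genes. Hoxd10 (log2 5.51 ± 1.07, adjusted p = 0.0387), Hoxa10 (2.60 ± 0.35, adjusted p = 0.000234), Hoxc10 (1.81 ± 0.27, adjusted p = 0.000827) and Hoxd9 (1.33 ± 0.26, adjusted p = 0.0425), which mark position along the body axis, were higher in KO. Hoxd10 read 2.32 ± 0.11 in the 4 sham WT arrays, near the floor, so that its difference is a lower bound. It read 7.84 ± 0.74 in the 4 sham KO arrays and had means of 4.74 to 6.99 in the injured groups of both genotypes. Egr2, a transcription factor of myelinating Schwann cells, was higher (2.19 ± 0.37, adjusted p = 0.00508), as were the zinc transporter gene Slc39a8 (0.96 ± 0.17, adjusted p = 0.0154) and Cd59a, an inhibitor of the complement membrane attack complex (0.87 ± 0.11, adjusted p = 0.000234). Slc34a3, a phosphate transporter gene, was lower (−0.80 ± 0.15, adjusted p = 0.0154).

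Markers of other tissue also averaged higher in sham KO, though not array by array with the Hox genes. In sham KO the means of 13 skeletal muscle genes (+2.98), 7 Schwann cell and nerve root genes (+1.13), 17 endothelial genes (+0.44) and 9 pericyte genes (+0.58) were higher by the list test with its preset correlation (adjusted p = 2.36e-08, 7.71e-07, 2.36e-08 and 1.66e-06). None of these calls held with an estimated correlation (adjusted p = 0.62, 0.134, 0.295 and 0.134 with an estimated correlation). The largest muscle differences, in Tnnc2 (4.26), Myh4 (3.88), Myl1 (3.87) and Acta1 (3.65), did not pass (adjusted p = 1 each). Of the Schwann cell genes Egr2 was called (3 adjusted over the list alone), and Pmp2 (2.79, adjusted p = 0.836) and Pmp22 (0.92, adjusted p = 0.688) were not. No muscle, endothelial or pericyte gene was called (0, and 0 adjusted over the list alone, by limma). The G2/M list averaged −0.21, with no gene called (adjusted p = 0.771 with an estimated correlation). The 63 proliferation genes averaged −0.10 (4.93 ± 0.14 in KO and 5.03 ± 0.10 in WT, exact permutation p = 0.257, 0.343 adjusted), and their call by the preset list test (adjusted p = 0.00519) was lost with the other (adjusted p = 0.599 with an estimated correlation). That call also ended without sham WT replicate 2 (−0.07), sham KO replicate 1 (−0.07) or the library labelled sham KO replicate 2 (−0.05), and with the mean of a gene's probe sets (−0.08). In all, 13 probe sets were called (9 higher, 4 lower, 1107 at an unadjusted p under 0.05). The count was 8 without sham KO replicate 4, 20 without the library labelled sham KO replicate 2, and 2 in a fit of only the arrays compared. It was 5 with the arrays with conflicting labels grouped by source and time, 25 without 3 arrays that stood apart, 47 without the filter and 91 with array weights.

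**Figure D3:**
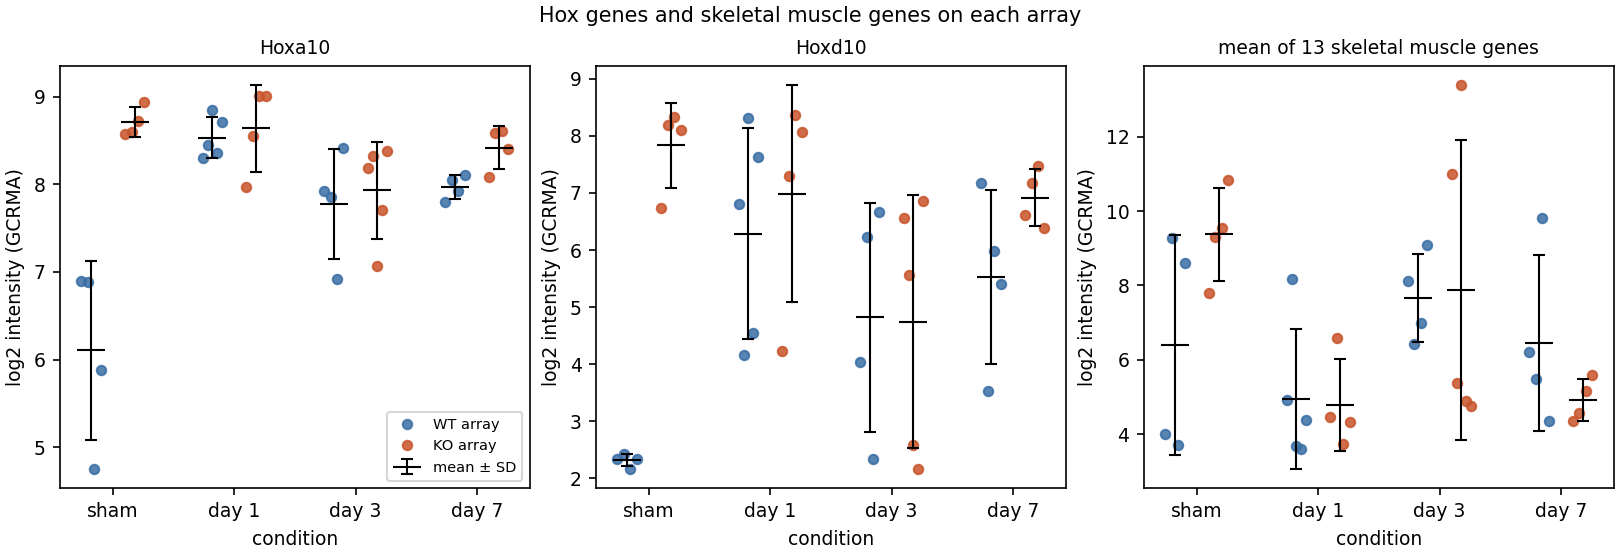
Log2 signal of Hoxa10 and Hoxd10 and the mean log2 signal of 13 skeletal muscle genes (vertical axes) for each array by condition and genotype, with mean and SD per group. Hoxd10 averaged 2.32 in sham WT and 7.84 in sham KO, and the muscle genes 6.40 and 9.38.

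At day 1 after injury, genes of cell division were lower in KO than in WT cords. Mki67, the standard marker of cycling cells, differed by log2 −3.52 ± 0.45 (11.5-fold, adjusted p = 1.64e-05, 3.75 ± 0.65 in 4 KO and 7.28 ± 0.64 in 5 WT arrays). It also read lower in KO in sham, without passing (−1.34 ± 0.47, adjusted p = 0.84). Top2a, the topoisomerase of mitotic chromosomes, differed by −2.88 ± 0.27 (adjusted p = 1.54e-07, a lower bound in size, since 1 KO array read the lowest value of that probe set, 3.69), and Cdk1, the kinase that starts mitosis, by −2.20 ± 0.20 (adjusted p = 1.54e-07). The other genes among the 10 largest decreases were Pbk (−2.72), a mitotic kinase, Rrm2 (−2.41), a subunit of ribonucleotide reductase, and Birc5 (−2.40) and Bub1 (−2.23, a lower bound in size) of the mitotic checkpoint machinery. They also held Cep55 (−2.33), which acts in the last step of cell division, the cyclin gene Ccna2 (−2.30) and Cdca5 (−2.26), which holds sister chromatids together. Of 23 G2/M genes 11 were lower (17 adjusted over the list alone, mean −1.19, adjusted p = 0.00582 with an estimated correlation). That list averaged only 3.17 in KO and 4.37 in WT, so differences of members at the floor are lower bounds in size. Of 22 DNA replication genes 7 were lower (20 adjusted over the list alone, mean −0.75, adjusted p = 0.00871 with an estimated correlation), among them Cdc6 (−1.58), Uhrf1 (−1.34) and Mcm5 (−1.01). Of 18 G1/S genes 3 were lower (7 adjusted over the list alone, mean −0.42, adjusted p = 0.105 with an estimated correlation), among them Ccne2 (−1.17) and Rbl1 (−1.10). Over the 63 proliferation genes the mean difference was −0.82 and the median −0.59, with 60 of 63 below 0 and 21 called (44 adjusted over the list alone, adjusted p = 0.00122 with an estimated correlation). Every KO array (5.274 to 5.476, mean 5.39 ± 0.09) lay below every WT array (6.029 to 6.487, mean 6.21 ± 0.18), with an exact two-sided permutation p of 0.00794, the smallest that 126 splits can give, and 0.0318 after adjustment over the 4 conditions.

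Interferon-induced genes were among those higher in KO at day 1. Samd9l (1.30 ± 0.30, adjusted p = 0.0311), the checkpoint ligand gene Cd274 (1.20 ± 0.26, adjusted p = 0.0248), the interferon-induced GTPase gene Igtp (1.14 ± 0.27, adjusted p = 0.0368), Cmpk2 (0.96 ± 0.18, adjusted p = 0.00464) and Stat2, which carries the interferon signal to the nucleus (0.90 ± 0.19, adjusted p = 0.0124), were higher than in WT. So were Scgb3a1 (1.44), Ddit4, an inhibitor of mTOR signalling (0.98), the kinase gene Dapk1 (0.95), the clock gene Npas2 (0.94) and Cd59a (0.86). The 20 interferon genes averaged +0.85, with 1 called (11 adjusted over the list alone). Their mean ran from 7.336 (replicate 2) to 8.714 (replicate 1) in the KO arrays and from 6.55 to 7.427 in the WT arrays, so the genotypes overlapped. The list call was lost with the other test (adjusted p = 0.39 with an estimated correlation). Usp18 (1.70, adjusted p = 0.289), Ifit1 (1.56, adjusted p = 0.366), Oasl2 (1.27, adjusted p = 0.374) and Ifit3 (1.25, adjusted p = 0.193) did not pass.

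Microglial genes averaged lower in KO at day 1. The 13 homeostatic microglia genes had a mean of −0.36, with Fcrls called (−0.92, 6 adjusted over the list alone, adjusted p = 0.432 with an estimated correlation) and Gpr34 (−0.96, adjusted p = 0.087) and P2ry12 (−0.88, adjusted p = 0.271) not past. No phagocytic or fibroblast gene was called by limma (0, and 0 adjusted over the list alone), with means of −0.36 over 23 and −0.47 over 25 genes (adjusted p = 0.432 and 0.925 with an estimated correlation). The fibroblast list ran from 7.256 (replicate 3) to 8.431 in KO and from 8.279 to 8.505 in WT, so 1 KO array weighs heavily on its mean. Of the 17 CDK inhibitor and p53 target genes, Cdkn2c was lower (−0.84, adjusted p = 0.0325), and Cdkn1a (+0.86, adjusted p = 0.225) and Cdkn1c (−0.49, adjusted p = 0.548) did not pass. The skeletal muscle list differed by a mean of −0.17, on which 1 array weighs heavily. It read 8.167 in day 1 WT replicate 2, 3.608 to 4.924 in the other WT arrays and 3.743 to 6.582 in KO. In all, 145 probe sets were called at day 1, 30 higher and 115 lower (113 by at least 1.5-fold). The count was 70 without day 1 KO replicate 4, 80 without day 1 WT replicate 4, 89 without day 1 KO replicate 3, 58 without the 2 arrays with conflicting labels and 23 with those arrays grouped by source and time. It was 86 in a fit of only the arrays compared, 93 with the day 7 KO arrays averaged, 216 without day 1 WT replicate 5, 234 with a replicate block, 384 without 3 arrays that stood apart and 535 with array weights.

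**Figure D4:**
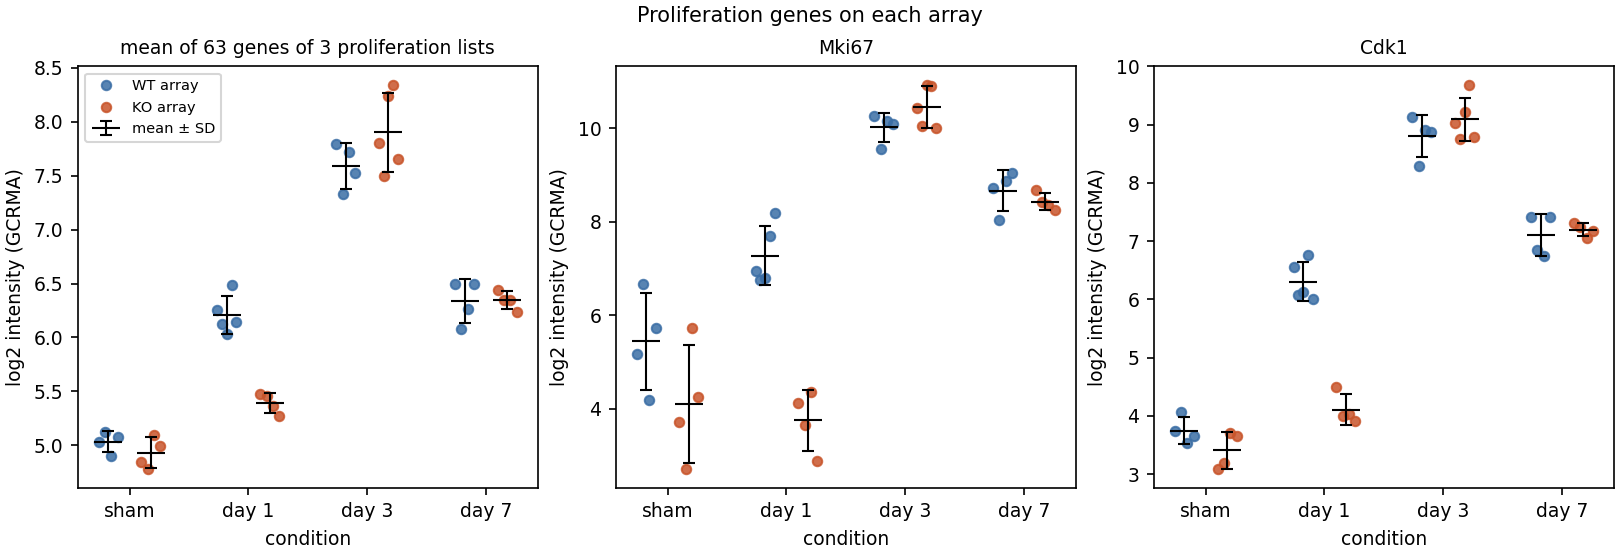
Mean log2 signal of 63 proliferation genes and log2 signal of Mki67 and Cdk1 (vertical axes) for each array by condition and genotype, with mean and SD per group. At day 1 the list mean ran from 5.274 to 5.476 in KO and from 6.029 to 6.487 in WT; at day 3 it ran from 7.495 to 8.338 and from 7.328 to 7.798.

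At day 3 the genotypes differed in few genes. Dapk1 (0.99 ± 0.14, adjusted p = 0.00023) and Cd59a (0.91 ± 0.11, adjusted p = 1.81e-05) were higher in KO, and Nkd1, an inhibitor of Wnt signalling (−0.59 ± 0.11, adjusted p = 0.0408), and Insig1, which holds back cholesterol synthesis (−0.52 ± 0.10, adjusted p = 0.0391), were lower. Of the 3 Nkd1 probe sets 1 had the opposite sign. Proliferation genes no longer read lower. Their mean difference was +0.31, with 0 called by limma (4 higher adjusted over the list alone). It was 0.205 without day 3 KO replicate 4, 0.416 without day 3 KO replicate 2 and 0.035 with array weights. They averaged 7.91 ± 0.37 in 5 KO and 7.59 ± 0.21 in 4 WT arrays, with an exact permutation p of 0.198 (0.343 adjusted). The preset list call (adjusted p = 2.76e-12) was lost with the other test (adjusted p = 0.14 with an estimated correlation). The 14 antigen presentation genes averaged +0.48 (0 called, 3 adjusted over the list alone, Cd74 1.05 and H2-Aa 1.01 not past) and the 16 monocyte genes +0.49 (0 called, 2 adjusted over the list alone, Ccr2 1.63 not past). The 15 cholesterol genes averaged −0.21 (1 called, 3 adjusted over the list alone). Each of these lists had adjusted p = 0.376 with an estimated correlation. The arrays of the genotypes overlapped. The monocyte list ran from 8.623 to 10.241 in KO, highest in replicate 3, and from 8.674 to 9.277 in WT. Antigen presentation ran from 7.633 to 8.737 in KO and from 7.152 to 7.925 in WT, lowest in replicate 2. The muscle list ran from 4.746 to 13.381 in the KO arrays and from 6.42 to 9.085 in the WT arrays. In all, 9 probe sets were called (5 higher, 4 lower, 2603 at an unadjusted p under 0.05). The count was 45 without day 3 KO replicate 2, 34 without day 3 KO replicate 5, 22 without day 3 WT replicate 1, 17 without day 3 WT replicate 4 and 6 without day 3 KO replicate 3. It was 15 with a replicate block, 17 without the filter and 2 in a fit of only the arrays compared.

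At day 7 Dapk1 (1.00 ± 0.14, adjusted p = 0.00062) and Cd59a (0.91 ± 0.11, adjusted p = 6.07e-05) were again higher in KO. Mcoln3, a cation channel gene of endosomes (−0.91 ± 0.17, adjusted p = 0.0306), and Capn6, a calpain gene (−0.71 ± 0.14, adjusted p = 0.0421), were lower. Proliferation genes averaged 6.34 ± 0.08 in KO and 6.34 ± 0.20 in WT (mean difference +0.01, median −0.01, exact permutation p = 0.886, 0.886 adjusted). That difference was below 0 without day 7 WT replicate 2 (−0.08), day 7 WT replicate 3 (−0.02) or day 7 KO replicate 1 (−0.03), and with array weights (−0.02) or centring (−0.02). The 20 interferon genes averaged +0.51, the 15 glutamate and dorsal horn genes +0.38, the 25 matrix genes −0.38 and the 13 muscle genes −1.55, with 0 called in each by limma (0 adjusted over the list alone, adjusted p = 0.754 each with an estimated correlation). The muscle list ran from 4.34 to 9.825 in WT, highest in replicate 3, and from 4.35 to 5.589 in KO. The matrix list ran from 8.462 to 10.324 in WT, highest in replicate 4, and from 8.912 to 9.314 in KO. Single WT arrays thus weigh heavily on both means. In all, 10 probe sets were called (4 higher, 6 lower, 1150 at an unadjusted p under 0.05). The count was 6 without day 7 WT replicate 1. The 4 day 7 KO arrays lay close together (median SD over probe sets 0.093), and with them averaged to 1 sample the count was 2. The labels call them biological replicates, and whether they shared RNA is not given in the sources used here, so the day 7 KO spreads, the exact p and the counts rest on that label. It was 18 in a fit of only the arrays compared and 286 with array weights.

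Over all 4 conditions, Dapk1 and Cd59a were higher in KO in each condition, although Dapk1 did not pass in sham (0.66, adjusted p = 0.111). Dapk1, a kinase gene of cell death and autophagy, was higher in KO by 0.90 ± 0.07 (adjusted p = 8.58e-10). Its levels were 7.29 ± 0.17, 7.00 ± 0.23, 7.48 ± 0.10 and 7.62 ± 0.11 in KO and 6.63 ± 0.29, 6.05 ± 0.19, 6.49 ± 0.24 and 6.62 ± 0.27 in WT in sham and at day 1, day 3 and day 7. Cd59a was higher by 0.89 ± 0.06 (adjusted p = 5.88e-12). Its levels were 10.05 ± 0.23, 10.23 ± 0.06, 10.11 ± 0.21 and 10.08 ± 0.04 against 9.18 ± 0.03, 9.37 ± 0.16, 9.21 ± 0.20 and 9.17 ± 0.17. In each condition every KO array lay above every WT array for both genes. Samd9l (0.84), Hoxa10 (0.83), Hoxc10 (0.61), Cmpk2 (0.47), the glucose transporter gene Slc2a12 (0.45) and Aopep (0.41) were also higher. The means of Hoxa10 and Hoxc10 came mainly from sham (2.60 and 1.81, against 0.07 to 0.45 after injury). Samd9l and Cmpk2 passed at day 1, and Slc2a12 and Aopep at no single condition. The 2 Aopep probe sets were called in opposite directions. Mki67 (−1.17), Top2a (−0.71), the neuropeptide gene Npb (−0.66), Nxpe4 (−0.55), Cdk1 (−0.54), the sterol desaturase gene Sc5d (−0.24), Sytl2 (−0.18) and the peroxisomal transporter gene Abcd3 (−0.15) were lower. The means of Mki67, Top2a and Cdk1 came mainly from day 1, and at day 3 these genes read higher in KO without passing (0.44, 0.41 and 0.28, adjusted p = 0.73, 0.575 and 0.6).

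Small shifts of whole lists appeared over the 4 conditions, and all were lost with an estimated correlation. The 20 interferon genes averaged +0.41 (0 called by limma, 13 adjusted over the list alone, adjusted p = 0.246 with an estimated correlation). The 15 cholesterol genes averaged −0.12 (1 called, 3 adjusted over the list alone, adjusted p = 0.162 with an estimated correlation) and the 16 myelin genes −0.11 (0 called, 5 adjusted over the list alone, adjusted p = 0.162 with an estimated correlation). Dapk1 and Aopep lie 8 and 16 tested genes away from Ntrk2 in the gene order of GRCm38.p6, a feature singled out after their values were seen. They were the 2 called among the 100 tested genes nearest to Ntrk2, where 0.134 were expected. Whether their differences follow from the loss of trkB.T1 was not tested. In all, 31 probe sets were called (13 higher, 18 lower, 17 by at least 1.5-fold). The count ran from 19 without day 7 KO replicate 4 to 136 without day 3 WT replicate 2, and was 10 with the day 7 KO arrays averaged, 12 with the arrays with conflicting labels grouped by source and time, 127 without 3 arrays that stood apart and 404 with array weights.

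The response to injury itself differed between genotypes at day 1, in genes of cell division. Pbk (−2.71 ± 0.44, adjusted p = 0.00373), Top2a (−2.62 ± 0.39, adjusted p = 0.00192), Cdca5 (−2.38 ± 0.31, adjusted p = 0.000531), Cep55 (−2.31 ± 0.33, adjusted p = 0.00122), Bub1 (−2.12 ± 0.41, adjusted p = 0.0235), Pclaf, a partner of the replication clamp (−2.11 ± 0.39, adjusted p = 0.0193), Ccna2 (−2.04 ± 0.34, adjusted p = 0.0051), Cdk1 (−1.86 ± 0.29, adjusted p = 0.00364) and Shcbp1 (−1.82 ± 0.33, adjusted p = 0.0157) had a smaller change from sham in KO than in WT. Hoxa10 was also among them (−2.50 ± 0.48, adjusted p = 0.0232) and differed between genotypes in sham. Mki67 (−2.18, adjusted p = 0.393) and Rrm2 (−1.88, adjusted p = 0.0572) did not pass. Of the 63 proliferation genes 4 were called (27 adjusted over the list alone, mean −0.71, p = 0.00441 with an estimated correlation for the pooled set). The G2/M and DNA replication lists, taken singly among all lists, had adjusted p = 0.11 each with an estimated correlation. The G2/M list averaged only 3.25 in sham KO and 3.46 in sham WT, so changes of members at the floor are truncated. All 17 probe sets called at day 1 were lower (13 genes, 1342 at an unadjusted p under 0.05). The count was 11 without sham KO replicate 3 and 10 without the 2 arrays with conflicting labels. It was 0 with those arrays grouped by source and time, a reading that their profiles argue against. It was 57 without 3 arrays that stood apart and 113 with array weights. Bub1 read 2.36 in day 1 KO and 2.40 and 2.29 in WT and KO sham, near the floor, and Top2a read its lowest value, 3.69, in 2 sham KO arrays, 1 sham WT array and 1 day 1 KO array. The changes of both from sham are truncated there, so their injury-by-genotype differences are inexact.

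At day 3 and day 7 few genes or none were called for a difference in response. At day 3, 0 probe sets were called by limma (1567 at an unadjusted p under 0.05). The smallest p-values, none past the threshold, belonged to Hoxa10 (−2.45), the phospholipase gene Plcg2 (+1.16) and Hoxc10 (−1.74), with adjusted p = 0.267 each, and to Nkd1 (−0.72) and Hoxd9 (−1.56), with adjusted p = 0.446 each. The values of Hoxa10, Hoxc10 and Hoxd9 came mainly from sham. There KO minus WT was 2.605, 1.811 and 1.327, against 0.156, 0.069 and −0.236 at day 3. The proliferation set had a mean of +0.42 (p = 0.0595 with an estimated correlation) and the muscle list −2.75. At day 7 Cnmd, an angiogenesis inhibitor gene of cartilage, was called (−1.93 ± 0.31, adjusted p = 0.0182, 907 probe sets at an unadjusted p under 0.05), and Tex15 (+1.30), Slc39a8 (−1.09), Egr2 (−2.28) and Hoxa10 (−2.15) were not (adjusted p = 0.524 each). Slc39a8, Egr2 and Hoxa10 were higher in KO in sham (0.961, 2.19 and 2.605), which enters these differences with its sign turned. The proliferation set had a mean of +0.11 (p = 0.62 with an estimated correlation). The day 3 count was 2 without the library labelled sham KO replicate 2 and 1 without sham WT replicate 4. The day 7 count was 3 without the library labelled sham KO replicate 2, 2 without day 7 WT replicate 2 or sham WT replicate 4, and 0 without day 7 WT replicate 1, day 7 KO replicates 1, 3 or 4, sham WT replicates 1 or 3, or sham KO replicates 3 or 4. Without the filter the counts were 6 at day 3 and 8 at day 7, and at day 7 it was 39 in a fit of only the arrays compared and 49 with array weights. Without 3 arrays that stood apart they were 1 and 4. At day 7 it was 0 with the stricter filter, a replicate block, the day 7 KO arrays averaged or the arrays with conflicting labels grouped by source and time.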

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

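The counts over other splits of the arrays were planned, and all other tests in these paragraphs were chosen after the results were seen. The tests of a heterozygous animal and of the cord level replaced earlier versions after their results were seen, and both versions are given.

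The lower level of proliferation genes in KO at day 1 stood out because the response to injury differed between genotypes: the pooled set had an injury-by-genotype mean of −0.715, and 17 probe sets passed. Arrays with conflicting labels were excluded as the whole cause, since the KO minus WT mean was −0.83 without them. A weaker injury response of all kinds in KO was also excluded: regressed on the day 1 response, the genes of the other lists had a slope only 0.004 times that of the proliferation genes (−0.056 to 0.073 with each array left out). A slower course of the whole injury response in KO cannot be told apart from a change in proliferation genes alone, because the ratio of slopes on the change from day 1 to day 3 was 0.501 and ran from 0.282 to 0.653, on both sides of the 0.5 needed. The lower day 1 level of proliferation transcripts may thus be part of a wider difference in course, which stays open. Chance is unlikely, but not excluded, for the counts behind it. They were 145 probe sets for KO against WT (2 of 100 splits as large, highest other 155) and 17 for injury by genotype (2 of 100, highest other 37). No adjustment was made for the number of split tests. The split with 37 exchanged sham WT replicate 3 with the library labelled sham KO replicate 2, and day 1 WT replicate 3 with day 1 KO replicate 4. The split with 155 exchanged day 1 WT replicates 1 to 4 with day 1 KO replicates 1 to 4. It kept the KO arrays together, so it is close to the real split with the names exchanged. The 145 include the Ntrk2 probe sets lost in KO.

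The library labelled sham KO replicate 2 lay far from its group on the Ntrk2 probe set 1435196_at, at 8.591 against 2.826 in the other 3 arrays. A swap with a sham WT library was excluded, since 0 of the 4 sham WT arrays lay on the KO side. A library of a wild-type animal was excluded because its linear signal lay below all sham WT arrays. As a share of the way from the other sham KO arrays to the sham WT mean, it was 0.514 on 1420838_at (sham WT arrays 0.863 to 1.205). On 1435196_at it was 0.451 (0.904 to 1.084), with a mean of 0.483 over both. A mixture with RNA of one of the 4 sham WT libraries was argued against by 3 genes: the mean of Hoxa10, Hoxc10 and Hoxd10, low in sham WT, lay 0.637 above the lowest of the other sham KO arrays, although Hoxa10 alone lay close to the lowest (8.595 against 8.578) and the whole profile correlated slightly more with sham WT (0.919) than with sham KO (0.899). A heterozygous animal, or a mixture with RNA of a WT animal not among those 4, remains a candidate explanation, since other probe sets that differed between genotypes lay at a mean share of 0.421 of the way from WT to KO (6 of 26 probe sets, from 0.122 to 0.714, SE over their 4 genes 0.126). Without Egr2, whose difference passed in sham alone of the 4 conditions, the mean over the other 3 genes was 0.519 (SE 0.112), and the earlier version of that test gave 0.729 over 11 probe sets, from −0.083 to 3.094, inside the needed 0.25 to 0.75 but with so wide a range that the explanation stays a hypothesis.

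Hoxd10 stood out in sham KO replicate 1, at 6.73 against 8.101 to 8.328 in the other 3 arrays. Hoxd9, Hoxa10, Hoxc10 and Hoxd10 were lower in sham WT than in sham KO. Of the other tested genes of groups 9 and 10, Hoxa9 (+0.23), Hoxb9 (+0.27) and Hoxc9 (−0.10, KO minus WT) did not pass. A genotype difference of the same size in all conditions was excluded. The Hox genes of groups 9 and 10 differed by a mean of 0.206 over day 1, day 3 and day 7 (−0.098 to 0.427) against 1.67 in sham, a mean that holds Hoxd10 near the floor in WT. A genotype difference confined to sham cannot be told apart from other differences between the sham samples. Muscle in the sample was excluded too: sham WT replicates 2 and 4 had more muscle signal (means of 9.287 and 8.613) than any day 1 KO array (at most 6.582), and every day 1 KO array still lay above every sham WT array in the mean of the 3 group 10 genes, by at least 1.229. The level of the cord that was sampled stays open as untested: the gap of 1.686 between the group 10 genes and those of groups 1 to 8 was measured on the genes whose calls raised the question, and the earlier version, 1.692 between the means of 21 genes against a summed SD of 2.077, decided nothing either. Chance could not be excluded for the sham count of 13 probe sets (2 of 35 splits as large, highest other 114, with sham WT replicate 3 and the library labelled sham KO replicate 2 exchanged), and that highest count points to a structure of the samples.

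Other single arrays were flagged by the gap to the nearest array relative to the range of their group, given here as values. A small gap can pass that rule where the other arrays lie close together. On 1435305_at day 1 KO replicate 1 read 9.816 (others 10.185 to 10.217). On 1446712_at day 1 WT replicate 5 read 3.896 (others 3.724 to 3.77) and day 1 KO replicate 1 read 3.36 (others 3.724 to 3.755). On 1458622_at sham WT replicate 2 read 11.144 (others 11.089 to 11.098) and day 1 KO replicate 1 read 10.442 (others 10.817 to 10.89). The mean of the skeletal muscle genes was 8.167 in day 1 WT replicate 2, 1 of the 2 arrays with conflicting labels (others 3.608 to 4.924). Of 96 groups tested for such an array 8 had one, where chance gives about 1 in 20, or 4.8. The injury-by-genotype count at day 7 was 1, the gene Cnmd, and 13 of 100 splits gave as many (highest other 33, and 3 others over 3 times the real count), so chance could not be excluded.

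Of the remaining counts, KO against WT at day 7 (10, 1 of 35 splits, highest other 3) and over the 4 conditions (31, 1 of 100, highest other 1) exceeded all other splits. Both hold Ntrk2 probe sets lost in KO, so the outcome was in part fixed in advance. Injured against sham also exceeded them in WT (13030, 15217 and 13173, highest other 11174, 5021 and 2807) and KO (10959, 15964 and 11644, highest other 7, 15074 and 1). The split with 11174 exchanged all sham WT arrays with day 1 WT replicates 1, 2, 4 and 5. That with 15074 exchanged all sham KO arrays with day 3 KO replicates 1, 3, 4 and 5. Splits that mix sham and injured arrays widen the spread within groups, so their low counts say little about chance. Chance could not be excluded for KO against WT at day 3, with 9 probe sets (30 of 100 splits, highest other 4808). There 20 of the other splits gave over 3 times the real count, which points to a structure among the day 3 samples other than genotype. For injury by genotype at day 3 the count was 0 by limma (1567 at an unadjusted p under 0.05), so that all 100 of 100 splits had to give as many (highest other 801) and the comparison says nothing about chance. Chance could not be excluded for the counts of gene lists past the preset test either: 12 in sham (4 of 35 splits, highest other 14), 11 at day 1 (57 of 100, highest other 23), 18 at day 3 (24 of 100, highest other 26) and 10 at day 7 (15 of 35, highest other 15).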

How the results depend on the processing

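The fits without 3 arrays that stood apart and with the day 7 KO arrays averaged were chosen after the data were seen, and the other alternatives were planned. The proliferation difference at day 1 kept its direction under all alternatives run (−0.863 to −0.749 with each array left out, −0.83 with the arrays with conflicting labels grouped by source and time). It also kept its call by the list test with the preset correlation. That test gave as many list calls in 57 of 100 splits of the day 1 arrays, so this says little. The pooled set was not retested with an estimated correlation or by exact permutation under the alternatives. The 2 Ntrk2 probe sets lost in KO kept direction and call, except for sham in the fit of only the arrays compared. Below, the cause of a changed value was not tested, except that fewer tested probe sets or fewer arrays follow from the alternative itself. With 33.7% of values near the floor, signal over background limits dim genes, and no difference below that level can be measured. A sex covariate was not run.

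Without the filter, KO against WT gave 47 probe sets in sham and 17 at day 3, and injury by genotype 6 at day 3 and 8 at day 7; the stricter filter gave 0 at day 7 for the latter. Array weights gave 91 in sham, 535 at day 1, 286 at day 7 and 404 over the conditions, 113 and 49 for injury by genotype at day 1 and day 7, and proliferation means of 0.035 (adjusted p = 0.1) at day 3 and −0.024 at day 7. The day 7 proliferation mean was −0.003 after quantile normalization and −0.017 after centring. With an intensity trend and a robust prior, 1437560_at passed over the conditions (adjusted p = 0.047). Without both arrays with conflicting labels the count was 58 at day 1 and 10 for injury by genotype at day 1. Grouped by source and time, they gave 5 in sham, 23 at day 1, 12 over the conditions, 5974 for WT day 1 against sham, and 0 for injury by genotype at day 1 and day 7.

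The replicate numbers were shown by no test to pair samples (in 0 pairs of groups did all correlations of same-numbered arrays exceed 0.1); with a replicate block the counts were 234 at day 1, 15 at day 3 and 0 for injury by genotype at day 7. Without the library labelled sham KO replicate 2, day 3 WT replicate 2 and day 3 KO replicate 3 together, they were 25 in sham, 384 at day 1, 127 over the conditions and 57, 1 and 4 for injury by genotype, with a sham proliferation mean of −0.055 (adjusted p = 0.236). With the day 7 KO arrays averaged they were 93 at day 1, 2 at day 7, 10 over the conditions, 4205 for KO day 7 against sham and 0 for injury by genotype at day 7. Fitting only the arrays compared gave 2 in sham, 86 at day 1, 2 at day 3, 18 at day 7, 39 for injury by genotype at day 7, and Ntrk2 differences in sham of −4.82 (adjusted p = 0.408) on 1420838_at and −5.45 (adjusted p = 0.398) on 1435196_at. With the mean of a gene's probe sets, sham proliferation was −0.084 (adjusted p = 0.0619).

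With an estimated correlation, list calls numbered 0 in sham, 2 at day 1, 0 at day 3, 0 at day 7 and 0 over the conditions, 1, 4 and 3 in injured WT, 1, 0 and 3 in injured KO, and 0 for each injury-by-genotype comparison. Reversed values were those of 1446712_at in sham (0.053 with weights, 0.086 by source and time, 0.005 without the 3 arrays), neurotrophin genes at day 1 (−0.059 with the mean of probe sets), and, without the 3 arrays, complement (0.112) and iron genes (0.01) in sham, neutrophil (−0.069) and glutamate genes (0.001) at day 3, and antigen presentation genes for injury by genotype at day 3 (−0.066).

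Leaving out 1 array at a time, the KO against WT counts ran from 8 (sham KO replicate 4) to 20 (the library labelled sham KO replicate 2) in sham, from 70 (day 1 KO replicate 4) to 216 (day 1 WT replicate 5) at day 1, from 6 (day 3 KO replicate 3) to 45 (day 3 KO replicate 2) at day 3, from 6 (day 7 WT replicate 1) to 12 (day 7 WT replicate 2) at day 7 and from 19 (day 7 KO replicate 4) to 136 (day 3 WT replicate 2) over the conditions; at day 1 the count was also 80 (day 1 WT replicate 4) and 89 (day 1 KO replicate 3), and at day 3 it was 22 (day 3 WT replicate 1), 17 (day 3 WT replicate 4) and 34 (day 3 KO replicate 5). Injury-by-genotype counts ran from 11 (sham KO replicate 3) to 24 (the library labelled sham KO replicate 2) at day 1, from 0 to 2 at day 3 and from 0 to 3 at day 7 (both highest without the library labelled sham KO replicate 2). The proliferation mean ran from −0.16 (sham KO replicate 3) to −0.055 (the library labelled sham KO replicate 2) in sham, where its preset list call also ended without sham WT replicate 2 (−0.073) and sham KO replicate 1 (−0.075), and from −0.078 (day 7 WT replicate 2) to 0.061 (day 7 WT replicate 4) at day 7, where it was also below 0 without day 7 WT replicate 3 (−0.016) and day 7 KO replicate 1 (−0.026). For 1446712_at the values ran from −0.062 (sham KO replicate 4) to 0.087 (sham WT replicate 3) in sham and from −0.128 (day 3 WT replicate 3) to 0.049 (day 3 WT replicate 1) at day 3. Of 820 differences of named genes, 782 kept direction and call without the arrays with conflicting labels, and the other 38 kept direction only.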

Other observations

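Several gene groups outside the account above moved with injury in both genotypes. Blood-derived monocyte and macrophage genes rose in WT, 14, 16 and 13 of 16 at day 1, day 3 and day 7 (14, 16 and 13 adjusted over the list alone, adjusted p = 0.0997, 0.0949 and 0.12 with an estimated correlation), and in KO, 12, 16 and 13 (14, 16 and 13 adjusted over the list alone, adjusted p = 0.119, 0.0773 and 0.091 with an estimated correlation). Lyve1, a receptor of perivascular macrophages, was higher by 5.60 in WT at day 1. Homeostatic microglia genes split at day 1 in WT, where P2ry12 (−2.80) and Siglech (−2.41) fell and Olfml3 (2.01) and Fcrls (1.90) rose, and 11 of 13 rose by day 7 (11 adjusted over the list alone, adjusted p = 0.113 with an estimated correlation). All 14 antigen presentation genes rose in WT at each time point (14 adjusted over the list alone each time, means 1.35, 1.83 and 2.30, adjusted p = 0.271, 0.184 and 0.113 with an estimated correlation). Of the immediate early genes 15, 14 and 13 of 19 were higher in WT at day 1, day 3 and day 7 (15, 14 and 13 adjusted over the list alone, adjusted p = 0.088, 0.195 and 0.337 with an estimated correlation), among them Atf3, a factor of injured neurons (4.43 at day 3 and 4.75 at day 7).

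Support cells changed as well. Of 8 ependymal and ciliated cell genes 4 fell in WT at day 1 (4 adjusted over the list alone, mean −1.10, adjusted p = 0.271 with an estimated correlation), with Ccdc153 at −2.62, and by day 7 1 was higher, Cfap126 (0.95). Myelin genes fell, 9, 12 and 8 of 16 in WT (9, 12 and 8 adjusted over the list alone), such as Ugt8a (−1.11 at day 1), which makes myelin galactolipids; the list test did not pass at day 1 (adjusted p = 0.127) and did at day 3 and day 7 (adjusted p = 0.429 and 0.529 with an estimated correlation). Endothelial genes rose in WT at day 1 and day 3 (14 and 15 of 17, 14 and 16 adjusted over the list alone, adjusted p = 0.421 and 0.219 with an estimated correlation) and 4 did at day 7, led at day 1 by Esm1, a marker of sprouting endothelium (4.77). Iron and oxidative stress genes rose in WT at day 3 (16 of 21 higher and 2 lower, 16 and 2 adjusted over the list alone, adjusted p = 0.0405 with an estimated correlation), among them Hmox1, the oxidase subunit genes Cyba (4.15) and Ncf1 (3.50).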
